A study of Anser anser with 2 samples.

How the data were processed

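Total RNA from liver was extracted with Trizol, fragments of 20 to 30 nt were isolated from 10 μg of it on a gel, and Illumina libraries were made, per the labels' protocols. Each group, control and overfed, has 1 library, and the groups were taken from the labels. The authors deposited, for each library, the read count of every distinct read sequence (tag) matched to a miRNA, with the best matching reference miRNA of any species, its family and an alignment score. The counts are whole numbers and not normalized. The deposited score equalled 2 for each match, less 1 for each mismatch and 3 for each gap, in all rows, and its lowest value was 20; it was not used further. The aligner, the miRNA database and its release are not given in the sources used here. Because tags without a miRNA match are not listed, the totals of 9178938 and 9737540 reads are totals of miRNA reads, not the depth of the whole libraries. At that depth 1 read was 0.109 reads per 1000000 listed miRNA reads (RPM) in the control and 0.103 in the overfed library, and a count of 0 allows up to 0.327 and 0.308 RPM (3 counts).

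Tags were summed over reference names of different species with the same miRNA name and arm. A name without a letter was joined with a lettered name of the same number when their reference sequences shared at least 18 bases in a row and all but 2 bases of the shorter; this joining was settled after the files had been seen. It gave 1215 mature miRNAs. A shortened read can match a short reference of another name, so miR-27d, miR-130c and miR-16c hold reads of near relatives, and members of the let-7 and miR-103 families that differ by few bases can share reads. The most common tags of miR-29a, miR-30b-3p and miR-125c differ only at their ends from those of miR-29c-3p, miR-30a-3p and miR-125b-5p, so these pairs can share reads too. Levels are in RPM. The ratio of overfed over control was given an exact conditional binomial (Clopper-Pearson) 95% interval, and shares an exact Clopper-Pearson interval. Reads are amplified copies without molecular identifiers, so intervals and floors cover counting error only. The median half-width of the interval was 0.37 log2 units for the 35 miRNAs from 10 to 20 RPM and 0.02 above 1000.

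The rule of size was fixed before the data were examined: a mean of at least 10 RPM, a ratio of at least 2 times in either direction and an interval that excludes 1. No p-value was computed, because miRNAs are not replicates. The 25 miRNA lists (liver cell types, lipid and glucose metabolism, fibrosis, inflammation, hypoxia, and families and clusters) were fixed at the same time; the median log2 ratio of each with at least 3 members past the minimum was placed among 10000 random lists matched on deciles of level, and a percentile under 2.5 or over 97.5 was taken as standing apart, as a description of these libraries. The text names the 10 most abundant miRNAs, the 10 largest increases and 10 largest decreases that met the rule (all where fewer), and per list the 4 most abundant members and any that met the rule; miR-33a-5p, the miR-29 members, miR-145-3p, miR-214-3p and the names in the closing section that fall outside this rule were chosen after their values were seen.

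On simulated counts for the 1215 miRNAs with the real levels and totals, the rule called 29 of the 29 past the minimum that were changed 3-fold, in the right direction, and 0 of the 31 changed 1.2-fold. Both sizes lie well away from 2 times, so this outcome was likely beforehand. Changes near 2 times, where several of the real calls lie, were not simulated. The simulated counts held Poisson counting noise only, with no variation between birds or libraries. The result therefore does not show that the calls would repeat in other birds. Alternatives were edgeR's TMM factors, DESeq2's median-of-ratios factors, scaling without miR-122-5p, other minimums, another pseudocount, merging by family and other sizes of the rule, and, chosen after seeing the data, names without joining, tags without a mismatch, names with a defined family only, and tags of at least 21 bases. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Genome positions of the miRNAs are not given, since the reference used here holds gene names without miRNA genes.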

Results

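Small RNA from goose liver was sequenced in 1 control and 1 overfed library. The birds were male Landes geese, a breed kept for fatty liver production, 90 days old, and 60 of them entered the experiment. Control geese ate a basal diet of 2873 kcal and 171 g protein per kg at will. Overfed geese received a diet rich in carbohydrate for 21 days, which held 3353 kcal per kg with 76 g of protein and 15 g of fat, and their liver is described as fatty. How many birds each library holds is not given in the sources used here. The control library listed 9178938 miRNA reads in 17203 distinct tags and the overfed library 9737540 reads in 18072 tags. With 1 library per group there is no replicate check and no test between conditions: every difference below is between these 2 libraries, and every interval covers counting error only.

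The first comparison asked which miRNAs differed between fatty and normal liver. Of 143 miRNAs with a mean of at least 10 reads per 1000000 listed miRNA reads (RPM), 10 were at least 2 times higher in the overfed library and 2 at least 2 times lower. miR-203-3p, a miRNA best known from stratified epithelium, had the highest ratio, with 43.1 RPM in the control and 219 in the overfed library and a log2 ratio of 2.34 (exact 95% interval 2.19 to 2.5). miR-222-3p, the most abundant of the 12, stood at 3429 and 10098 RPM, a log2 ratio of 1.56 (1.54 to 1.58). miR-375, known from pancreatic islets, stood at 67.0 and 168 RPM (log2 ratio 1.33, 1.19 to 1.46). miR-2954, a miRNA of birds encoded on the Z chromosome and more abundant in males, stood at 106 and 42.1 RPM (log2 ratio -1.33, -1.50 to -1.16), and miR-146c, of a family induced in inflammation, at 40.1 and 17.4 (log2 ratio -1.21, -1.48 to -0.94).

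The other miRNAs at least 2 times higher were miR-4492 (log2 ratio 1.2), miR-499 (1.18), which lies in a myosin gene, miR-3182 (1.13), miR-365-5p (1.11), miR-139-3p (1.06), miR-193a-5p (1.01) and miR-184-3p (1.01, 0.95 to 1.06). The counting interval lay wholly beyond 2 times for miR-203-3p, miR-222-3p, miR-375, miR-4492 and miR-2954. miR-4492 and miR-3182 belong to 19 names whose family the files list as undefined, and whether their reads come from miRNAs was not tested. No read of miR-3182 matched its reference without a mismatch, while 98.3% of miR-4492 reads did. The most common miR-4492 tag overlaps those of miR-4508 and miR-4674, also of undefined family, so miR-4492 is not separate evidence from them. The median over the 19 names was 0.424%, against 93.8% for names with a family. Without the 19 names 8 miRNAs were higher. With tags of at least 21 bases, miR-139-3p (log2 ratio 0.52), miR-365-5p (0.94) and miR-3182 no longer met the rule. Between the libraries 104 of the 143 miRNAs differed by less than 1.5 times, and log2 levels correlated across the 143 miRNAs with a Pearson r of 0.984 and a Spearman rho of 0.955, where miRNAs are not independent replicates. Scaling decided part of the list: edgeR's TMM factors lowered all log2 ratios by 0.23, which left 3 miRNAs higher (miR-203-3p, miR-222-3p and miR-375) and 7 lower, with miR-30d-5p, miR-30a-5p and miR-29c-3p among the lower ones. DESeq2's factors gave 7 higher and 4 lower, without miR-139-3p, miR-184-3p (log2 ratio 0.92) and miR-193a-5p (0.92), and miR-193a-5p also missed the rule with 1 RPM added (0.99); with names not joined, the part of its reads listed as miR-193 star met the rule in its place. With both arms and all letters of a number summed, neither lower call was kept: miR-2954 was at -0.86 (-1.01 to -0.72) and miR-146 at 0.06. Of the higher calls, miR-139-3p, miR-193a-5p and miR-365-5p were not kept either. The miR-146 sum could not show a change of miR-146c, which had 368 control and 169 overfed reads, against 22890 and 25539 for miR-146b-5p. Scaling without miR-122-5p gave 21 higher and 4 lower.

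**Figure D1:**
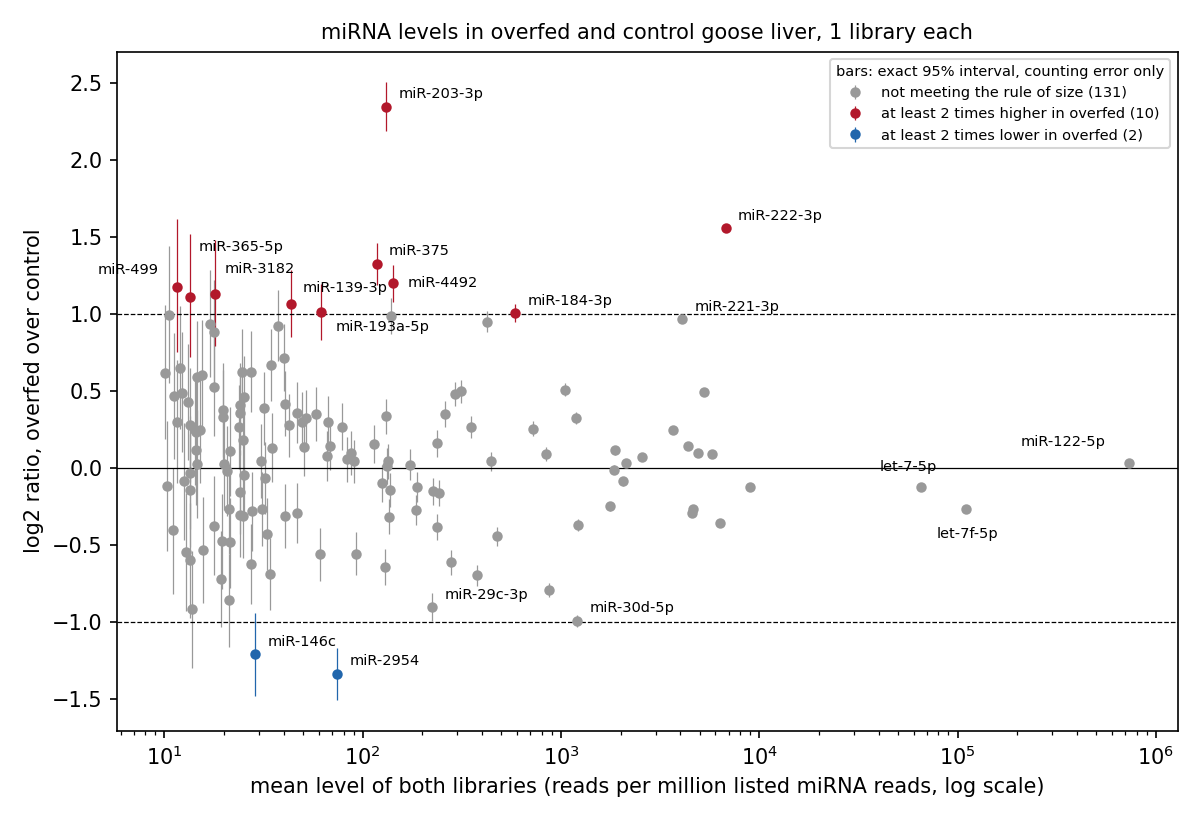
Each point is 1 of the 143 miRNAs, with its mean level in both libraries (RPM, log axis) and its log2 ratio of overfed over control, scaled to the total of listed reads; bars are exact 95% counting intervals and dashed lines mark 2 times. The 10 red points lie at log2 ratios from 1.01 to 2.34 and the 2 blue points at -1.21 and -1.33, while miR-122-5p lies at 0.03.

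The second comparison asked which miRNAs made up the liver profile. miR-122-5p, the hepatocyte miRNA, held 72.7% of miRNA reads in the control library (exact 95% interval 72.6% to 72.7%) and 74.4% in the overfed library (74.3% to 74.4%). The 10 most abundant miRNAs held 95.5% and 95.2%. The let-7 family, regulators of cell proliferation and of insulin signalling, came next, with 20.9% of control reads and 18.2% of overfed reads. let-7f-5p had 120435 and 100195 RPM (log2 ratio -0.27), let-7-5p, listed without a letter, 68601 and 62903 (-0.13), and let-7g-5p 7102 and 5556 (-0.35). let-7b-5p and let-7i-5p had log2 ratios of 0.09 and 0.10, which were below 0 with TMM factors and, at -0.05 and -0.44, with tags of at least 21 bases. miR-140-3p had a log2 ratio of -0.12, miR-101a-3p of -0.26 and miR-107 of 0.50. miR-107 and miR-103a-3p share their most common tags but for the last base, so their family total, with a log2 ratio of 0.36 (0.35 to 0.38), is the safer value.

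Lists of liver, lipid and signalling miRNAs, fixed before the data were examined, were then compared by the percentile of their median log2 ratio among 10000 random lists of like size and level. Of the 17 lists placed this way, only the fibrosis list stood apart. Of 100 random lists of 10 miRNAs drawn from these libraries, 5 fell outside the same range, a share set by the threshold itself. A list standing apart among 17 can therefore arise without a shift. The fibrosis list stood lowest, at percentile 1.23, with a median of -0.28 over 12 members, of which 7 were lower and 5 higher beyond counting error. The lower ones were miR-199-3p (-0.29), miR-214-3p, miR-200a-3p, miR-200b-3p and the miR-29 members, which target collagen genes: miR-29c-3p (-0.90), miR-29b-3p (-0.43) and miR-29a (-0.59). The most common miR-29a tag was that of miR-29c-3p without its last base, so miR-29a and miR-29c-3p can share reads. miR-199-3p and miR-214-3p also belong to the stellate or mesenchymal list, whose median was likewise -0.28 with 5 of 6 members lower. The higher ones were miR-222-3p, miR-221-3p (log2 ratio 0.96), miR-221-5p (0.99) and both arms of miR-21, with miR-21-5p at 0.14, which was below 0 with TMM factors and at -0.15 with tags of at least 21 bases. The summed reads of the list were higher in the overfed library, with a log2 ratio of 0.63; miR-221 and miR-222 gave 57798 of its 146767 control reads and 152829 of its 240707 overfed reads. With a minimum of 100 RPM the median turned to 0.55, and the list no longer stood apart without a minimum (percentile 8.78), with tags without a mismatch (2.52) or with defined families only (2.54). No direction of fibrosis is read from the median of this list.

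None of the 30 members of the lipid metabolism list met the rule of size: 10 were higher and 13 lower beyond counting error, with a median of -0.08 at percentile 5.26. Its most abundant members after miR-122-5p were miR-107, miR-128-3p (log2 ratio 0.03) and miR-103a-3p (-0.01). miR-33a-5p, encoded within a sterol regulator gene and named here after its value was seen, stood at 259 and 366 RPM (0.50, 0.42 to 0.57). Of the 24 members of the insulin and glucose list, 7 were higher and 12 lower beyond counting error, 1 of them (miR-375) meeting the rule, with a median of -0.05 at percentile 6.71. The list of miRNAs reported in fatty liver had 17 members, 10 higher and 6 lower beyond counting error, among them miR-222-3p and miR-146c meeting the rule in opposite directions, with a median of 0.14 at percentile 78.9. In the inflammation list, miR-21-5p, miR-146b-5p (0.07), miR-181a-5p (0.05) and miR-142-5p (0.06) lay close to 0, each below 0 with TMM factors, while miR-223-3p was at 0.62 and miR-146c (-1.21) met the rule; the median of its 10 members was 0.11 at percentile 52.7. The hypoxia list (miR-210) had no member past the minimum and summed to 12.4 and 13.2 RPM.

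Cell type lists gave the following. Hepatocyte miRNAs went both ways, with 3 of 7 members above and 3 below 0 in each scaling and a median of 0.03 at percentile 44.7 (-0.19 with TMM factors); miR-148a-3p stood at 465 and 287 RPM (-0.69), miR-122-3p at 0.48 and miR-365-5p met the rule. Of the 6 stellate or mesenchymal miRNAs, 5 were lower beyond counting error, miR-199-3p at -0.29, miR-143-3p at -0.25, miR-145-5p at -0.56 and miR-145-3p and miR-214-3p also, and miR-143-5p was at 0.10 (-0.35 with tags of at least 21 bases). The median of -0.28 lay at percentile 2.55. The other arm of miR-199, miR-199a-5p, is not on this list and was at 0.15 (0.03 to 0.28). It met the rule with tags of at least 21 bases, so its value depends on the tags used. Leukocyte miRNAs went both ways, with miR-223-3p at 0.62, miR-142-5p at 0.06 and miR-146c at -1.21 (median 0.06, percentile 43.3). The red cell miRNAs miR-451a and miR-144-3p had log2 ratios of -0.12 and -0.31, and the minor arm of miR-144 one of 0.43, with a list median of -0.12 at percentile 22.7. The arms of the endothelial miR-126 were at 0.30 for miR-126-5p and -0.31 for miR-126-3p, a median of -0.01. In the list of biliary or other epithelium, miR-200a-3p (-0.29) and miR-200b-3p (-0.72) were lower while miR-203-3p met the rule (median -0.29, percentile 14.9). Of the muscle list, miR-1a-3p was at 0.09 and miR-499 met the rule (median 0.63), and of the pancreas list only miR-375 passed the minimum. Neuronal miRNAs summed to 1.53 and 2.98 RPM, with none past the minimum.

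**Figure D2:**
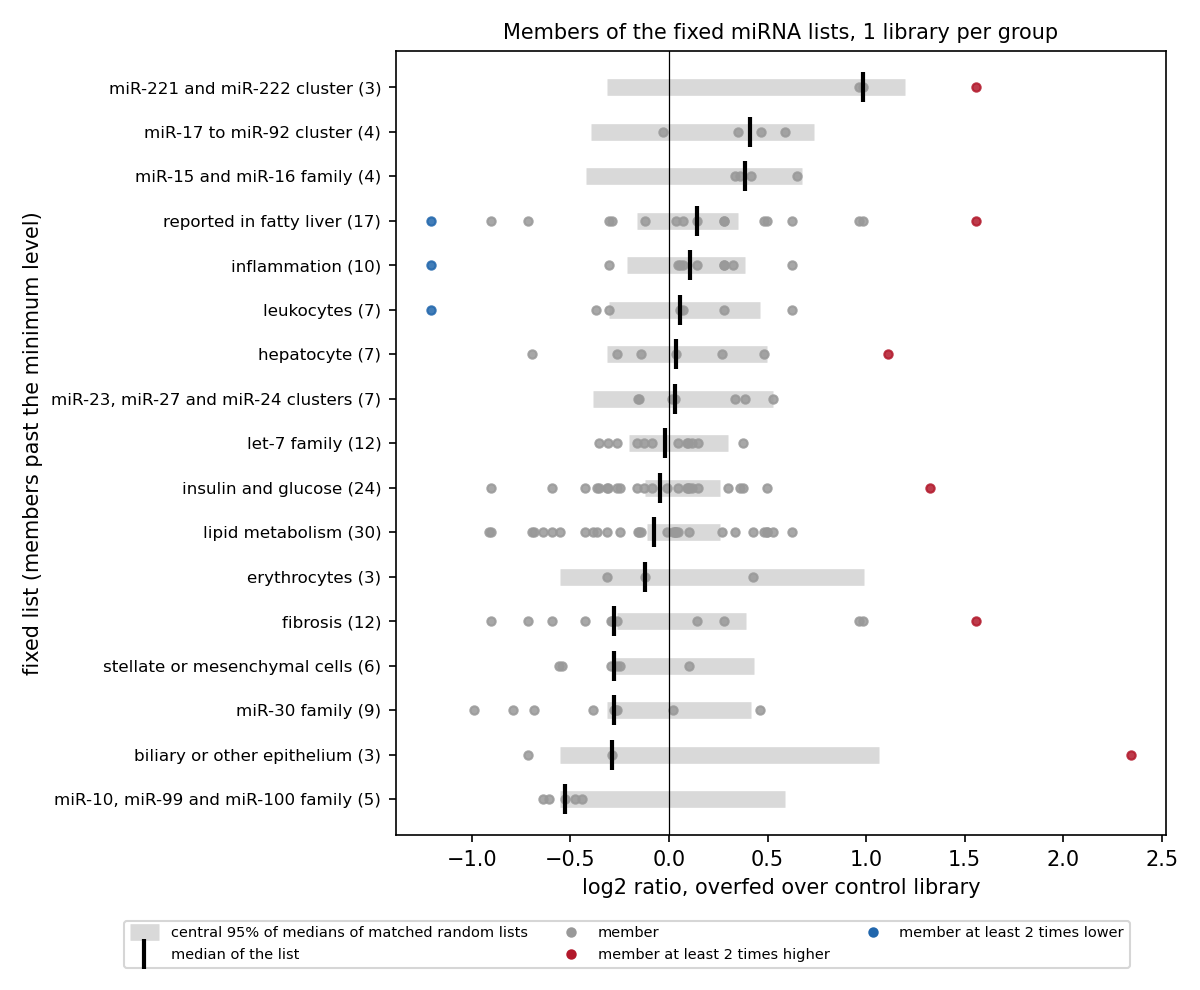
Points are the members of each fixed list with at least 3 members past the minimum level, placed at their log2 ratio of overfed over control library; black ticks are list medians and grey bars the central 95% of medians of matched random lists. The fibrosis median of -0.28 lies just outside its grey bar, and that of the miR-221 and miR-222 cluster, 0.99, inside it.

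Among families and clusters, the miR-221 and miR-222 cluster stood highest, with all 3 members above 0 in each scaling tried and a median of 0.99 at percentile 96.5. Each scaling shifts all log2 ratios by 1 constant, so the scalings are not separate evidence. Over all 143 miRNAs, 59 were above and 50 below 0 in each scaling. The miR-10, miR-99 and miR-100 family, with miR-125, stood lowest: miR-10a-5p was at -0.44, miR-100-5p at -0.61, miR-125b-5p at -0.64 and miR-125c at -0.47. All 5 members were below 0 in each scaling, and the median of -0.53 lay at percentile 3.42. The most common miR-125c tag was that of miR-125b-5p with an A added, so these members are not separate evidence. Only 3.01% of miR-125c reads had no mismatch, and its value of 0.16 with tags without a mismatch rests on those few reads. In the miR-30 family 7 of 9 members were below 0 in each scaling, with miR-30d-5p at 1599 and 806 RPM (-0.99, -1.03 to -0.95), miR-30a-5p at -0.79, miR-30c-3p at -0.38 and miR-30e-5p at -0.27, and a median of -0.28 at percentile 5.91. The most common miR-30b-3p tag was that of miR-30a-3p shifted by 1 base, so miR-30b-3p and miR-30a-3p can share reads. All 4 members of the miR-15 and miR-16 family were above 0 in each scaling (miR-16c 0.42, miR-16-5p 0.36, miR-15b-5p 0.33, miR-15a-5p 0.65), although miR-15b-5p was at -0.31 with tags of at least 21 bases, with a median of 0.39 at percentile 78.5. Of the miR-17 to miR-92 cluster, miR-92a-3p was at 0.35 (-0.25 with tags of at least 21 bases), miR-92 at 0.59, miR-19b-3p at 0.47 and miR-17-5p at -0.03 (median 0.41, percentile 80.0). miR-363-3p, alone of its cluster past the minimum, was at 0.35 (-0.04 with tags of at least 21 bases). The miR-23, miR-27 and miR-24 clusters had a median of 0.03 (percentile 46.7), with miR-24-3p at -0.15 (0.25 with tags without a mismatch), miR-23a-3p at 0.01, miR-27d-3p at 0.34 and miR-23b-3p at 0.39. With tags of at least 21 bases miR-27d-3p was at -2.07, which rests on few reads, since its mean read length was 18.04 nt in the control and 18.03 nt in the overfed library. The let-7 family had a median of -0.02 (percentile 22.3), with 5 of its 12 members below 0 and 1 above 0 in each scaling. The miR-183 cluster (1.53 and 1.03 RPM) and the miR-34 family (1.53 and 3.18) had no member past the minimum.

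The last comparison was of read forms. miR-122-5p was read mostly as the 22 nt tag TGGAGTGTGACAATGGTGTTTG, 46.3% of its reads in the control library and 48.5% in the overfed library, and as the same tag without its last base, 26.2% and 27.2%. The forms 1 base longer that end in T, 17.1% and 15.2%, and in A, 3.90% and 2.58%, were scarcer in the overfed library; whether that base is encoded in the precursor or added later was not tested. The form 1 base longer with T was also scarcer for let-7f-5p (16.3% and 14.1%), let-7-5p (30.5% and 25.6%) and miR-222-3p (39.0% and 33.0%). Among 51 miRNAs with at least 1000 reads in each library, this form was scarcer in the overfed library for 36, beyond counting error for 22, and more common beyond counting error for 0. Reads shortened at the 3′ end were more common for 41 of the 51. Over all reads, 24.5% in the control and 20.9% in the overfed library had 23 nt or more.

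**Figure D3:**
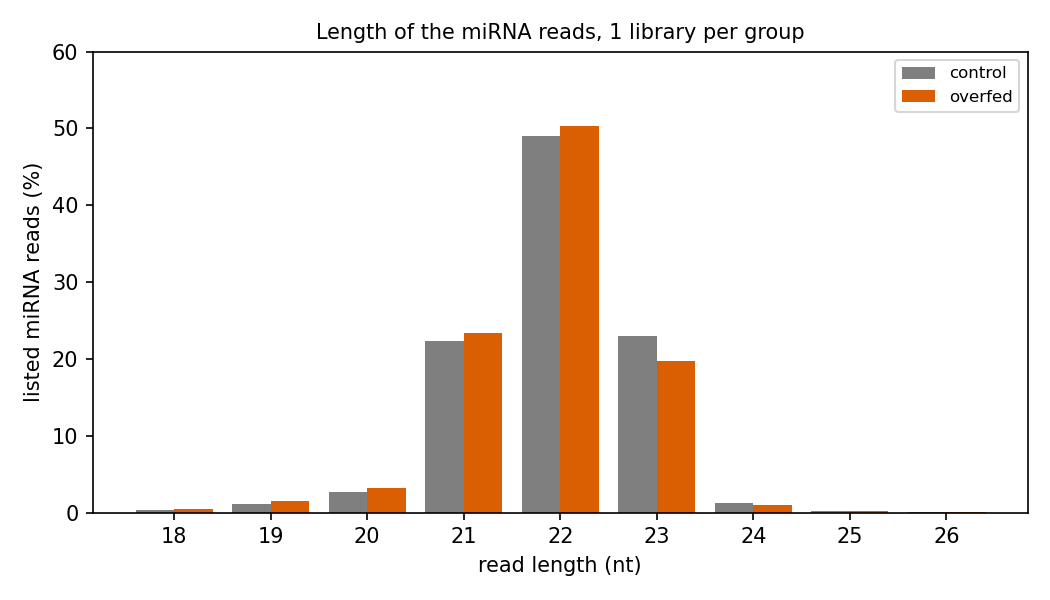
Bars give the share of listed miRNA reads (%) at each read length (nt) in the control (grey) and the overfed (orange) library. Reads of 23 nt made up 23.01% in the control and 19.7% in the overfed library.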

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

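No paired analysis was possible because each group has 1 library, and leaving out a replicate could not be run. The planned total of all listed reads as a base for the shares was not run separately, since all tags carried a miRNA name and the total is the same. Names without joining, tags without a mismatch, names with a defined family only and tags of at least 21 bases were chosen after seeing the data.

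Against 12 miRNAs meeting the rule of size (10 higher, 2 lower), TMM factors gave 3 higher and 7 lower, sharing 5 of the 12; the log2 shift of 0.23 accounts for this by construction. Median-of-ratios factors gave 4 lower, and scaling without miR-122-5p gave 25 (21 higher, 4 lower) where 194 miRNAs passed the minimum and log2 ratios were 0.09 higher. Without a minimum there were 47 (38 higher, 9 lower), and with a minimum of 100 RPM 5 (5 higher, 0 lower), with more and fewer miRNAs compared. Merging by family gave 7 (0 lower), since arms and letters are summed, with miR-2954 at -0.86 and miR-146, mostly reads of miR-146b-5p, at 0.06. The higher calls miR-139-3p, miR-193a-5p and miR-365-5p were lost as well. A rule of 1.5 times gave 39 (25 higher, 14 lower) and of 4 times 1 (1 higher, 0 lower, miR-203-3p). Tags of at least 21 bases gave 14 (9 higher, 5 lower), sharing 9 of the 12: miR-139-3p (1.06 to 0.52), miR-365-5p and miR-3182 were lost, and miR-148a-3p, miR-199a-5p, miR-221-5p, miR-2478 and miR-425-3p gained; the cause was not tested. The remaining alternatives, with 1 RPM added, names without joining, tags without a mismatch or defined families, gave totals from 10 to 12.

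Of 130 list medians under alternatives, 114 stayed on their side of the percentile threshold. A change of scaling shifts all log2 ratios by 1 constant. It can move a percentile only through the miRNAs that pass the minimum or the matching on level. The count of 114 is therefore not a count of separate checks. The fibrosis median turned from -0.28 to 0.55 (percentile 98.4) with a minimum of 100 RPM, and was no longer past the threshold without a minimum (-0.085), with tags without a mismatch (-0.30, percentile 2.52) and with defined families (-0.28, percentile 2.54). Without a minimum, the lipid metabolism (-0.085), miR-30 (-0.28), miR-10 (-0.46) and miR-221 (0.98) medians passed it; with a minimum of 100, the list reported in fatty liver did (0.31). The stellate or mesenchymal median passed it with median-of-ratios factors (-0.37), without miR-122-5p (-0.19) and with 1 RPM added (-0.27). The miR-10 family passed it with defined families (-0.53), and the miR-221 cluster without miR-122-5p (1.07), with tags without a mismatch (0.99) and with defined families (0.99). The value of -0.085 is that of any miRNA with equal counts in both libraries. The cause of these changes was not tested.

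With tags without a mismatch, miR-122-5p held 72.4% and 74.6% of reads and the 10 most abundant 96.1% and 96.0%. The Pearson r was 0.975 with a minimum of 100 RPM, over 57 miRNAs in place of 143. Depth limits the low miRNAs: the interval of the log2 ratio was 0.37 wide to each side from 10 to 20 RPM, so calls near 2 times there (miR-499, miR-365-5p, miR-3182) rest on few reads.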

Other observations

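The arms of some miRNAs moved apart. The minor arm of miR-2954 held 10.6% of the reads of both arms in the control library (exact 95% interval 8.81% to 12.6%) and 35.4% in the overfed library (31.7% to 39.3%), since it was higher (log2 ratio 0.88) while the main arm was lower (-1.33). The minor arm of miR-146c held 23.2% and 45.8%. miR-139-5p held 31.6% and 20.8% of miR-139 reads, and miR-126-3p 31.7% and 23.2% of miR-126 reads. The arms of miR-221 kept their proportions, with miR-221-5p at 3.26% and 3.31%.

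Names without a defined family made up 19 of the 143 miRNAs past the minimum, and 17 of these had a ratio above 1, with a median log2 ratio of 0.41 against 0.04 for the other 124. They held 0.270% of control reads and 0.379% of overfed reads. Some of their most common tags overlap, among them those of miR-4508, miR-4492 and miR-4674, and those of miR-2487 and miR-2981. The 17 are therefore not all separate evidence. The most common tags of the 19 names had a median GC content of 60.0%, against 45.5% for the others. miR-2779 ended in CCA in 98.7% and 99.1% of its reads, against 0.0189% and 0.0190% of reads with a defined family. The other 7 of the 8 most abundant of these names ended so in at most 0.380% of reads. Among the less abundant ones, the most common tags of miR-5097, miR-2478 and miR-4454 also ended in CCA.

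The tests of epithelium, of the level of pancreatic miRNAs, of RNA breakage and of stellate cells below were chosen only after the results they concern had been seen. The biological explanation that the design gives, overfeeding, cannot be tested with 1 library per group.

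miR-203-3p, miR-375 and miR-184-3p were higher in the overfed library (miR-184-3p under 2 times with TMM or DESeq2's factors), and other tissue in the sample is a candidate source. Epithelium would bring miR-200a, miR-200b, miR-429 and miR-141, but their summed reads were lower, with a log2 ratio of -0.39 (-0.55 to -0.24), which argues against it. Pancreatic tissue would bring miR-216 and miR-217, but their summed reads were 1 in each library, at most 0.572 RPM in the overfed library by the upper exact Poisson bound, against a rise of 101 RPM for miR-375, which argues against it. Their log2 ratio, the test first planned, was -0.085 with an interval from -6.38 to 6.21 and decided nothing. Islet cells without the rest of the pancreas were not tested.

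Reads of most miRNAs were shorter in the overfed library, 109 of 143 by their mean length, with a median difference of -0.09 nt. Random breakage of RNA would also shorten the 5′ end, and the share of reads starting inside the usual start was higher in the overfed library for 37 of 51 miRNAs, or 72.5%, but beyond counting error higher for 6 and lower for 2, against 25 and 0 for reads shortened at the 3′ end. Size selection on the gel would lower long miRNAs, and the log2 ratio correlated with tag length across the 143 miRNAs with a Spearman rho of -0.301, just past the -0.3 set in advance. Both may contribute, on weak evidence, and a difference in how the 3′ ends are formed in fatty liver was not tested.

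miR-29, miR-30 and the miR-10, miR-99, miR-100 and miR-125 members were lower together, 15 of 17 below 0 with a median log2 ratio of -0.47, a set put together after these values were seen, whose fixed parts, the miR-30 and miR-10 lists, lay inside the range of random lists (percentiles 5.91 and 3.42). By their most common tags, miR-29a, miR-30b-3p and miR-125c can share reads with miR-29c-3p, miR-30a-3p and miR-125b-5p. The count and the bootstrap treat them as separate members. A fit on GC content and length of the sequence over the other 126 miRNAs did not predict these low values. The median residual of the members was -0.65 (bootstrap 95% interval -0.72 to -0.47). Because the members were chosen after their low values were seen and were left out of the fit, a low residual was likely beforehand. GC content and length are therefore not excluded. The highest median over 4 scalings was -0.38. Each scaling shifts all log2 ratios by the same constant, at most 0.09 upward, so this value follows from the size of the shifts. It covers only the scalings tried, and no conclusion on scaling is drawn from it. A smaller share of stellate or mesenchymal cells in the overfed sample could account for part of the low values: their list had a median of -0.28 (bootstrap interval -0.55 to -0.07), and its difference from the members' median had an interval from -0.11 to 0.45. That list holds both arms of miR-143 and of miR-145, which the bootstrap treats as separate, and it leaves out miR-199a-5p, at 0.15. The bootstrap intervals describe the members used and do not show that the set of 17 stands apart.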
